A study of Mus musculus with 27 samples.

How the data were processed

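ATAC-seq libraries were made by the submitters at day 2 from aliquots of 50000 unsorted cells with 12 PCR cycles and sequenced with reads of 100 bp, per the labels. The submitters' processing notes name Bowtie2, Picard and featureCounts without versions and the mouse build mm9. The deposited table holds raw counts per region and library, which the authors made with featureCounts and did not normalise, and its values are whole numbers whose totals differ between libraries. How the regions were defined, which reads were removed and whether reads or fragments were counted is not stated. The table has 30815 regions of 201 to 1484 bp (median 234 bp) and 24 columns, for 27 labelled samples. The 3 samples of dsRed cells with the inhibitors have no column in it, so the control was the dsRed group without inhibitors, and an effect of the inhibitors was not estimated. Samples were grouped by their labels.

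Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Regions were kept by filterByExpr with its minimum count of 10 and minimum total of 15, which left 20494 (66.5%). Libraries were scaled by TMM, and the 8 groups were fitted together in a negative binomial model with edgeR's quasi-likelihood test, with a square root of the common dispersion of 0.29. The 22 comparisons were 7 with the control, 9 additions of a factor to cells with another factor or a pair, 3 averages of these and 3 interactions. P-values were adjusted by Benjamini-Hochberg within each comparison, and regions with an adjusted p under 0.05 are called. The SE of a log2 fold change is its size divided by the square root of the quasi-likelihood F. Levels are CPM on the TMM scale, and log2 CPM used a prior count of 2. A region higher than the control in a factor group is called opened and one lower closed, as names for the direction of the counts.

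The comparisons, the rule for named regions and most alternatives were set before the data were examined. The rule takes, for each comparison with the control, the 3 called regions with the highest and the 3 with the lowest log2 fold change, and 1 of each for additions and averages. It asks for a mean log2 CPM at or above the median of the regions tested and, outside averages, for groups whose libraries do not overlap. It adds up to 5 regions where GMT differs from all 3 pairs, on each side. The alternatives were RLE size factors, total counts alone, loess offsets against the mean count (span 0.3), DESeq2, no filter, a stricter filter, fits with only the compared groups, the replicate number as a block, a minimum fold of 1.5 by glmTreat, and leaving out each library or each replicate number. Sets of regions were tested with fry of limma, with the regions picked in libraries other than those tested. Shared calls were compared with 20 simulations of unchanged groups, in which control, G, M and T counts were all drawn at the fitted control level. A further 20 simulations left only G unchanged, with M and T at their fitted levels. Shared calls were also compared with 1000 random lists matched on mean count in 20 bins.

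The test was tried on simulated data with the depths of the 24 libraries, where 50 regions were changed in each direction at each of 2 fold changes. For G against the control at a fold of 4, 29 of those raised and 15 of those lowered were called, and at a fold of 2, 5 and 3, with 4 false calls among 14175 regions. For GMT against the control they were 32 and 14 at a fold of 4 and 4 and 4 at a fold of 2, so falls were called less often than rises at a fold of 4. Intervals for count ratios cover counting error only. The gene annotation at hand is of GRCm38, and on 9 chromosomes regions end beyond its last gene, so regions were not assigned to genes. Gene lists, distances to transcription start sites, motifs and matching on GC content were therefore not used.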

Results

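Chromatin accessibility was measured by ATAC-seq, in which a transposase inserts sequencing adapters into open chromatin, in immortalised neonatal mouse cardiac fibroblasts that express large T antigen and carry an alpha-MHC-GFP reporter. The cells received retroviruses for 3 cardiac reprogramming factors, the zinc-finger protein Gata4 (G), the MADS-box protein Mef2c (M) and the T-box protein Tbx5 (T), alone, in pairs or all together, and were harvested unsorted at day 2. Counts were analysed for 30815 regions in 24 libraries, 3 in each of 8 groups named control, G, M, T, GM, GT, MT and GMT. The control received a retrovirus for the red fluorescent protein dsRed. All 7 factor groups were cultured with the TGF-beta inhibitor SB431542 and the Wnt inhibitor XAV939, per the labels, and the control was not. Every comparison with the control therefore holds the factors and the inhibitors together, whereas the 15 comparisons between factor groups are matched for the inhibitors. A further 3 samples, dsRed cells with the inhibitors, are not analysed here. Total counts ran from 241394 in GMT replicate 1 to 1704896 in MT replicate 1, with a median of 661976. The lowest and highest totals within a group were 457816 and 1204778 in the control, 386147 and 1544120 in G, 456282 and 1031724 in M, and 382527 and 676886 in T. In the combinations they were 407184 and 1558476 in GM, 424913 and 1179791 in GT, 428197 and 1704896 in MT, and 241394 and 1059307 in GMT. The labels call the replicates biological without saying what separates them, so the p-values measure the spread between these samples.

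The libraries were first compared over the 20494 regions tested. Spearman correlations across regions had a median of 0.8535 between libraries of one group, from 0.688 to 0.944, and of 0.686 between libraries of different groups. The first principal component of log2 CPM held 29.5% of the variance and placed 11 of the 12 libraries labelled with Tbx5 above 0 and the 12 without Tbx5 below 0. The exception was the library labelled GT replicate 1. Its correlations with the G libraries were 0.824 to 0.941, above its 0.722 and 0.73 with the other GT libraries. Its counts differed from those of G replicate 1 with a chi-square of 1.44 per degree of freedom. With G replicates 2 and 3 it was 2.61 and 4.25, and with GT replicates 2 and 3 it was 7.23 and 3.97. G replicate 1 and the other G libraries had 3.53 and 3.71, and all pairs of one group 1.42 to 7.23. Mean correlations with another group also exceeded those with the own group in 3 other libraries, each with the lowest total count of its group. GMT replicate 1 had 0.707 with GMT, 0.772 with MT and 0.75 with the control, and its 0.688 with GMT replicate 2 was the lowest value within a group. G replicate 2 had 0.802 with G and 0.823 with the control, and GM replicate 2 0.804 with GM and 0.815 with the control. Separate fits, each without only the one of these libraries in its factor group, called 4535 regions in G versus control, 3132 in GM versus control and 8166 in GMT versus control. With all libraries the counts were 3213, 2510 and 6869. The library labelled GT replicate 1 carried the label GT, so it stayed in the comparisons, and counts without it, an alternative chosen after the data were examined, are printed beside those with it.

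**Figure D1:**
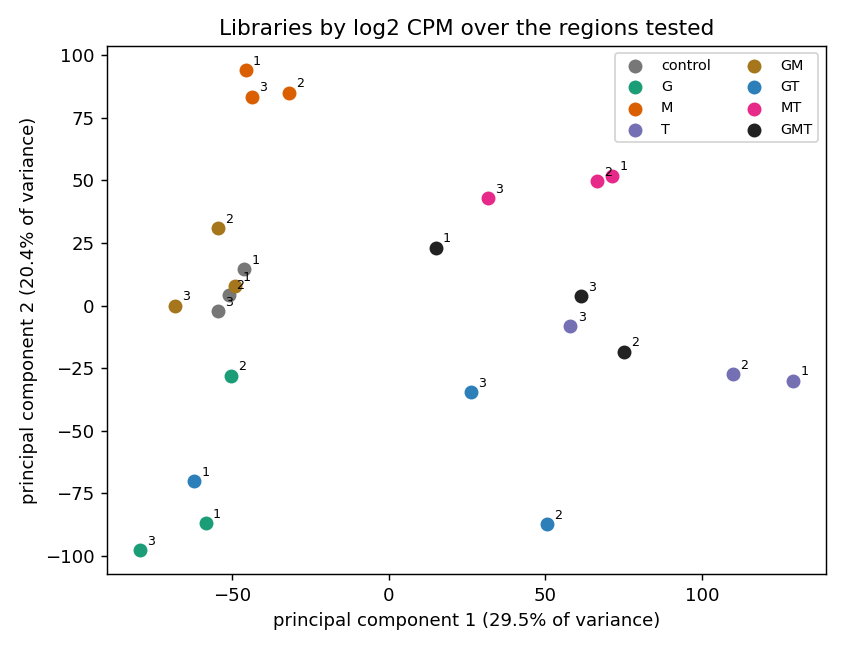
Principal components 1 (horizontal axis, 29.5% of the variance) and 2 (vertical axis, 20.4%) of log2 CPM over the 20494 regions tested, 1 point per library with its replicate number, colours for the 8 groups. The library labelled GT replicate 1 lies at -62.1 on the first component, beside the G libraries, while GT replicates 2 and 3 lie at 50.5 and 26.1.

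The comparison of G with the control asked which regions changed in cells given Gata4 and the inhibitors. Regions are named by their mm9 coordinates, since no gene annotation of that build was used here, and log2 fold changes are given ± SE. The regions named are the top-ranked by log2 fold change among called regions with a mean level at or above the median and libraries of the groups that do not overlap. The highest-ranked region that rose was chr15:80081059-80081398 (log2 fold change 4.03 ± 0.78, adjusted p = 0.000996), where G had 28.9 ± 15.4 CPM (SD, n = 3) and the control 1.69 ± 1.49 CPM. The next were chr18:36624709-36625199 (log2 fold change 3.90 ± 0.71, adjusted p = 0.000576) and chr18:61657249-61657815 (log2 fold change 3.75 ± 0.51, adjusted p = 8.93e-05). The top-ranked fall was at chr13:16831540-16832001 (log2 fold change -3.47 ± 0.47, adjusted p = 8.93e-05), from 88.8 ± 25.9 CPM in the control to 9.19 ± 5.54 CPM in G. It was followed by chr5:103006152-103006453 (log2 fold change -3.26 ± 0.69, adjusted p = 0.00191) and chr2:131130981-131131242 (log2 fold change -3.13 ± 0.47, adjusted p = 0.000114). In G versus control, 1970 regions were higher and 1243 lower by edgeR's quasi-likelihood test (adjusted p below 0.05), with median log2 fold changes of 2.08 and -1.74. Regions higher in G had a median control level of 10.6 CPM and a median width of 276 bp, against 50.4 CPM and 248 bp for regions lower in G. The number of regions called was 1792 without control replicate 2, 1508 without control replicate 3, 1318 without G replicate 1, 1409 without G replicate 3, 1519 without replicate 1 of all groups and 2 without replicate 3 of all groups, against 3213 with all libraries. The fit without replicate 3 of all groups had 3040 regions at an unadjusted p under 0.05 and called none of the 6 regions named here. Without the library labelled GT replicate 1 in the fit there were 2306 higher and 1495 lower.

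In M against the control, cells given Mef2c and the inhibitors were compared with control cells. The highest-ranked region that rose was chr18:26069730-26069989 (log2 fold change 4.53 ± 0.59, adjusted p = 4.95e-06), where M had 181 ± 58.6 CPM (SD, n = 3) and the control 8.33 ± 3.28 CPM. The next were chr11:32846515-32846968 (log2 fold change 4.52 ± 0.43, adjusted p = 7.08e-08) and chr3:52890609-52891176 (log2 fold change 4.43 ± 0.60, adjusted p = 8.27e-06). The top-ranked fall was at chr5:72641179-72641570 (log2 fold change -3.78 ± 0.61, adjusted p = 5.76e-05), from 199 ± 19.9 CPM in the control to 15.3 ± 7.94 CPM in M. It was followed by chr17:84242883-84243476 (log2 fold change -3.61 ± 0.57, adjusted p = 4.64e-05) and chr6:122639898-122640102 (log2 fold change -3.57 ± 0.59, adjusted p = 8.11e-05). In M versus control, 1982 regions were higher and 1326 lower by edgeR's quasi-likelihood test (adjusted p below 0.05), with median log2 fold changes of 2.23 and -1.67. Regions higher in M had a median control level of 9.59 CPM and a median width of 283 bp, against 58.4 CPM and 254.5 bp for regions lower in M. The number called was 2110 without control replicate 2, 1757 without control replicate 3, 1923 without M replicate 2, 1197 without replicate 2 of all groups and 1104 without replicate 3 of all groups, against 3308 with all libraries, and a fit with only these 6 libraries called 5257, 2547 higher and 2710 lower. Without the library labelled GT replicate 1 in the fit there were 2210 higher and 1597 lower.

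In T against the control, the cells compared had been given Tbx5 and the inhibitors. The highest-ranked region that rose was chr15:53424078-53424606 (log2 fold change 5.28 ± 0.71, adjusted p = 4.6e-06), where T had 176 ± 53.5 CPM (SD, n = 3) and the control 4.36 ± 0.418 CPM. The next were chr6:83523907-83524532 (log2 fold change 5.05 ± 0.76, adjusted p = 1.71e-05) and chr8:125937758-125938064 (log2 fold change 5.01 ± 0.54, adjusted p = 3.56e-07). The top-ranked fall was at chr13:100154886-100155180 (log2 fold change -4.10 ± 0.54, adjusted p = 3.53e-06), from 87.2 ± 12.1 CPM in the control to 5.05 ± 1.27 CPM in T. It was followed by chr1:129518975-129519343 (log2 fold change -4.08 ± 0.56, adjusted p = 5.39e-06) and chr4:119458919-119459319 (log2 fold change -3.61 ± 0.60, adjusted p = 4.74e-05). In T versus control, 2977 regions were higher and 2176 lower by edgeR's quasi-likelihood test (adjusted p below 0.05), with median log2 fold changes of 2.35 and -1.82. Regions higher in T had a median control level of 10.4 CPM and a median width of 313 bp, against 51.3 CPM and 243 bp for regions lower in T. The number called was 3390 without T replicate 2 and 2361 without replicate 2 of all groups, against 5153 with all libraries, and a fit with only these 6 libraries called 4867. Fitted without the library labelled GT replicate 1, the counts were 3176 higher and 2400 lower.

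The lists of the single factors, each against the same control without inhibitors, were then compared. Regions higher than the control were mostly called in 1 factor only, 6060 of 6486 (93.4%), and 17 were called in all 3. Of the regions lower than the control, 2240 of 3408 (65.7%) were called in 1 factor only and 169 in all 3. G and M shared 101 higher regions, G and T 207 and M and T 152, where independent lists of those lengths share 191, 286 and 288. For lower regions the shared numbers were 298, 560 and 648, where independent lists share 80.4, 132 and 141. Unchanged groups simulated against one shared control, itself simulated, shared 0 regions in either direction in all 20 simulations. That value leaves out the effects and gives no level for lists with real changes. The log2 fold changes of all regions tested correlated at 0.14 for G and M, 0.24 for G and T and 0.23 for M and T, and the simulated unchanged groups at 0.51, 0.46 and 0.45. Covariances were 0.17, 0.34 and 0.35, and 0.18 in the simulations for each pair. The control has 3 libraries and could not be split into parts of at least 2, so part of the excess over independent lists may come from the shared control. In the overlap of regions changed by single factors, 1168 regions were lower in 2 or 3 single factors, against 610 without control replicate 2, 601 without control replicate 3, 690 without replicate 1 of all groups, 318 without replicate 2 of all groups and 220 without replicate 3 of all groups. There were 2063 with only the compared groups in each fit, 520 with a minimum fold of 1.5 and 390 at an adjusted p below 0.01. The regions higher in 2 or 3 single factors numbered 426, against 227 without control replicate 2, 134 without control replicate 3, 273 without G replicate 1, 275 without G replicate 3, 263 without replicate 1 of all groups, 181 without replicate 2 of all groups and 58 without replicate 3 of all groups.

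The pairs were compared with the same control, again with factors and inhibitors together. In GM the top-ranked rise was at chr3:52890609-52891176 (log2 fold change 4.80 ± 0.59, adjusted p = 4.86e-06), at 88 ± 41.8 CPM in GM and 3.18 ± 1.66 CPM in the control, the region ranked 3 in M. It was followed by chr7:87645938-87646689 (log2 fold change 4.18 ± 0.53, adjusted p = 7.24e-06) and chr12:33285452-33285984 (log2 fold change 4.16 ± 0.79, adjusted p = 0.000935). Its top-ranked falls were at chr2:131130981-131131242 (log2 fold change -3.27 ± 0.48, adjusted p = 6.78e-05) and chr10:98859421-98859624 (log2 fold change -3.06 ± 0.45, adjusted p = 5.88e-05). In GT the top-ranked rise was at chr15:80081059-80081398 (log2 fold change 4.92 ± 0.75, adjusted p = 9.16e-05), at 55.6 ± 49 CPM in GT and 1.69 ± 1.49 CPM in the control, also ranked 1 in G. The top-ranked fall in GT was at chr13:16831540-16832001 (log2 fold change -3.62 ± 0.48, adjusted p = 3.02e-05), also ranked 1 in G. In MT the top-ranked rise was at chr3:8893449-8894002 (log2 fold change 4.91 ± 0.56, adjusted p = 4.87e-07), at 158 ± 13.5 CPM in MT and 5.89 ± 4.32 CPM in the control, and the top-ranked fall at chr17:73727120-73727326 (log2 fold change -2.98 ± 0.55, adjusted p = 0.000225). In GM versus control, 1742 regions were higher and 768 lower. In GT versus control, 2681 regions were higher and 1191 lower, and in MT versus control, 3578 regions were higher and 1475 lower. Offsets fitted by loess against the mean count gave 1296 higher and 978 lower in GM, 2016 higher and 1501 lower in GT and 2507 higher and 1947 lower in MT. Without the library labelled GT replicate 1, GT had 2882 higher and 1100 lower, GM 2024 higher and 1024 lower and MT 3994 higher and 1744 lower. The number called was 2510 for GM, against 1175 without control replicate 2, 757 without control replicate 3, 949 without GM replicate 1, 1399 without GM replicate 3, 1183 without replicate 1 of all groups and 44 without replicate 3 of all groups. It was 3872 for GT, against 2151 without control replicate 2, 1636 without control replicate 3, 1411 without GT replicate 2, 335 without replicate 2 of all groups and 621 without replicate 3 of all groups. For MT it was 5053, against 3356 without control replicate 2, 2782 without control replicate 3, 2638 without MT replicate 1, 3320 without replicate 1 of all groups, 2130 without replicate 2 of all groups and 2500 without replicate 3 of all groups. In edgeR fits (adjusted p in parentheses), the call at chr12:33285452-33285984, GM versus control, was lost without replicate 3 of all groups (0.11).

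With all 3 factors and the inhibitors, the top-ranked rise against the control was at chr15:80081059-80081398 (log2 fold change 5.82 ± 0.74, adjusted p = 3.32e-06), with 104 ± 63.2 CPM (SD, n = 3) in GMT. There the levels were 28.9 ± 15.4 CPM in G, 36.1 ± 7.75 CPM in T, 8.47 ± 3.12 CPM in M and 1.69 ± 1.49 CPM in the control, whose libraries had 0 to 3 counts there. The next, chr12:33285452-33285984 (log2 fold change 5.16 ± 0.77, adjusted p = 1.87e-05), stood at 101 ± 52.7 CPM in GMT, 50.8 ± 20.5 CPM in GM, 43 ± 21.7 CPM in MT and 33.1 ± 36.8 CPM in GT. The single factors had 16.4 ± 4.25 CPM in M and 15 ± 3.68 CPM in T. G had 3.74 ± 3.65 CPM and the control 3.6 ± 4.69 CPM, with 0 to 4 counts per control library. The next was chr3:52890609-52891176 (log2 fold change 4.80 ± 0.59, adjusted p = 2.7e-06). The top-ranked falls were at chr17:73727120-73727326 (log2 fold change -3.40 ± 0.58, adjusted p = 8.25e-05), from 118 ± 21.5 to 12 ± 3.64 CPM, and at chr9:34087253-34087453 (log2 fold change -3.35 ± 0.64, adjusted p = 0.000238). The next was chr18:15148797-15148997 (log2 fold change -3.18 ± 0.73, adjusted p = 0.00144). In GMT versus control, 4718 regions were higher and 2151 lower. Loess offsets gave 3098 higher and 2675 lower. Of the 4718 higher regions, 3401 (72.1%) were also higher in at least 1 single factor, and 472 in no single factor or pair. Of the 2151 lower regions, 1369 (63.6%) were also lower in a single factor and 645 in no single factor or pair. These shares set calls against the same control and do not test a difference between groups. The number called was 4175 without control replicate 3, 3997 without GMT replicate 2, 4123 without GMT replicate 3, 2400 without replicate 2 of all groups and 1271 without replicate 3 of all groups, against 6869 with all libraries. Fitted without the library labelled GT replicate 1, the counts were 5170 higher and 2452 lower. In edgeR fits (adjusted p in parentheses), the call at chr18:15148797-15148997, GMT versus control, was lost without replicate 3 of all groups (0.0775).

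**Figure D2:**
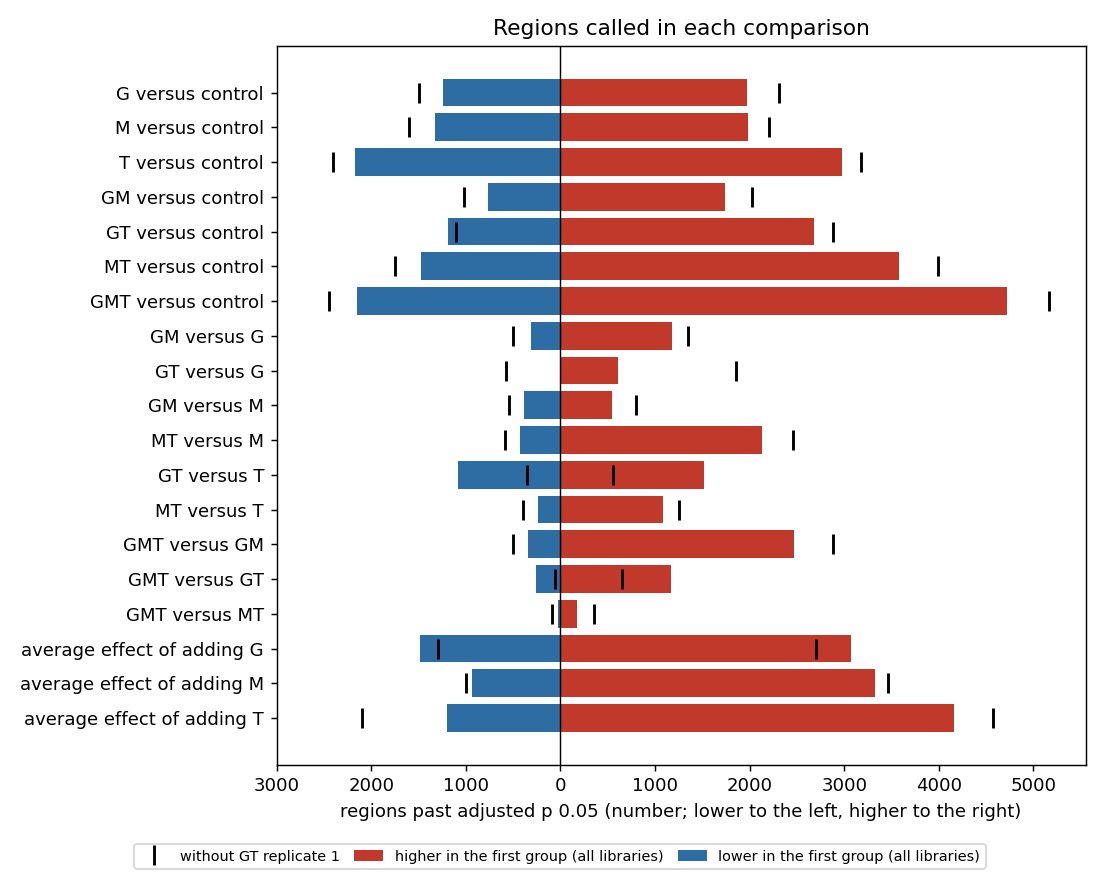
Number of regions (horizontal axis) past an adjusted p of 0.05 in each comparison (vertical axis), higher in the first group to the right and lower to the left, with black ticks for the counts without the library labelled GT replicate 1. GMT against the control had 4718 regions higher and 2151 lower, and GT versus G moved from 604 higher and 8 lower to 1860 higher and 581 lower without that library.

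The change on adding Gata4 to cells that already had Mef2c, Tbx5 or both was measured between groups that all had the inhibitors. Averaged over the 3 backgrounds, the top-ranked rise was at chr5:107876951-107877176 (log2 fold change 3.02 ± 0.33, adjusted p = 1.86e-07) and the top-ranked fall at chr2:6911839-6912415 (log2 fold change -2.42 ± 0.21, adjusted p = 5.14e-09). Added to M, G gave its top-ranked rise at chr5:107876951-107877176 (log2 fold change 3.62 ± 0.55, adjusted p = 0.00034), from 6.78 ± 3.19 to 77.7 ± 27.5 CPM. Its top-ranked fall was at chr2:6911839-6912415 (log2 fold change -2.94 ± 0.36, adjusted p = 2.44e-05). On the background of T, G gave its top-ranked rise at chr5:107876951-107877176 (log2 fold change 4.26 ± 0.60, adjusted p = 0.000109), from 5.08 ± 2.98 to 96.3 ± 84.8 CPM. There its top-ranked fall lay at chr6:87116686-87117212 (log2 fold change -3.57 ± 0.46, adjusted p = 0.000101). With the pair MT, G gave its top-ranked rise at chr2:69654566-69654966 (log2 fold change 3.29 ± 0.72, adjusted p = 0.0195), from 4.44 ± 3.45 to 38.1 ± 23.3 CPM. Its top-ranked fall in this case was at chr3:21463315-21463517 (log2 fold change -1.97 ± 0.42, adjusted p = 0.0185). In numbers, 542 regions were higher and 384 lower in GM than in M, 1518 and 1081 in GT than in T, 172 and 30 in GMT than in MT, and 3069 and 1486 for the average effect of adding G. In the same order, loess offsets gave 411 higher and 574 lower, 1180 higher and 1329 lower, 88 higher and 34 lower and, on average, 2468 higher and 2063 lower. Without the library labelled GT replicate 1 the counts were 796 higher and 549 lower in GM versus M, 552 higher and 355 lower in GT versus T, 355 higher and 90 lower in GMT versus MT and 2701 higher and 1291 lower on average. The number called was 926 for GM versus M, against 253 without M replicate 1, 177 without M replicate 2, 487 without GM replicate 1, 188 without GM replicate 3, 328 without replicate 1 of all groups, 236 without replicate 2 of all groups and 38 without replicate 3 of all groups. That for GT versus T was 2599, against 1125 without T replicate 1, 893 without T replicate 2, 271 without replicate 1 of all groups and 771 without replicate 2 of all groups. The number for GMT versus MT was 202, against 1 without MT replicate 1, 0 without MT replicate 2, 113 without MT replicate 3, 674 without GMT replicate 1, 11 without GMT replicate 2, 2 without GMT replicate 3, 486 without replicate 1 of all groups, 0 without replicate 2 of all groups and 2 without replicate 3 of all groups. For the average effect of adding G it was 4555, against 2336 without replicate 1 of all groups, 2150 without replicate 2 of all groups and 2890 without replicate 3 of all groups. Beside the 0 of edgeR without MT replicate 2 and without replicate 2 of all groups stood 2319 and 1287 regions at an unadjusted p under 0.05, and DESeq2 with all libraries called 277. In edgeR fits (adjusted p in parentheses), the call at chr2:69654566-69654966, GMT versus MT, was lost without MT replicate 1 (0.205), MT replicate 2 (0.0825), MT replicate 3 (0.0528), GMT replicate 2 (0.179), GMT replicate 3 (0.0962), replicate 2 of all groups (0.285) or replicate 3 of all groups (0.291). Likewise, the call at chr3:21463315-21463517, GMT versus MT, was lost without MT replicate 1 (0.15), MT replicate 2 (0.108), GMT replicate 2 (0.177), GMT replicate 3 (0.0843), replicate 1 of all groups (0.0581), replicate 2 of all groups (0.435) or replicate 3 of all groups (0.0959). Total counts as the only scaling gave 1859 higher and 815 lower in GT versus T, and fits with only the compared groups called 1581 in GM versus M, 984 in GT versus T and 111 in GMT versus MT.

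Mef2c was added to cells with Gata4, Tbx5 or both, with the inhibitors in every group. Averaged over the 3 backgrounds, the top-ranked rise was at chr4:64237548-64237799 (log2 fold change 3.78 ± 0.34, adjusted p = 7.45e-10) and the top-ranked fall at chr6:36780524-36780843 (log2 fold change -1.60 ± 0.27, adjusted p = 2.95e-05). Added to G, M gave its top-ranked rise at chr12:33285452-33285984 (log2 fold change 4.25 ± 0.77, adjusted p = 0.000595), from 3.74 ± 3.65 to 50.8 ± 20.5 CPM. Its top-ranked fall was at chr2:180301775-180302104 (log2 fold change -2.19 ± 0.44, adjusted p = 0.00192). On the background of T, M gave its top-ranked rise at chr2:84624028-84624336 (log2 fold change 4.42 ± 0.63, adjusted p = 6.68e-05), from 1.86 ± 1.9 to 48.3 ± 6.34 CPM. There its top-ranked fall lay at chr14:66890247-66890740 (log2 fold change -2.16 ± 0.56, adjusted p = 0.016). With the pair GT, M gave its top-ranked rise at chr15:59419636-59420074 (log2 fold change 4.05 ± 0.61, adjusted p = 9.54e-05), from 4.6 ± 2.54 to 66.4 ± 33.4 CPM. Its top-ranked fall in this case was at chr15:66629417-66629622 (log2 fold change -2.43 ± 0.59, adjusted p = 0.0104). In numbers, 1183 regions were higher and 307 lower in GM than in G, 1085 and 238 in MT than in T, 1164 and 263 in GMT than in GT, and 3323 and 939 for the average effect of adding M. In the same order, loess offsets gave 983 higher and 557 lower, 677 higher and 434 lower, 735 higher and 434 lower and, on average, 2532 higher and 1988 lower. Without the library labelled GT replicate 1 the counts were 1350 higher and 504 lower in GM versus G, 1252 higher and 398 lower in MT versus T, 651 higher and 53 lower in GMT versus GT and 3460 higher and 994 lower on average. The number called was 1490 for GM versus G, against 597 without G replicate 1, 358 without G replicate 3, 662 without GM replicate 1, 328 without replicate 1 of all groups and 72 without replicate 3 of all groups. That for MT versus T was 1323, against 595 without T replicate 1, 330 without T replicate 2, 744 without MT replicate 1, 539 without MT replicate 2, 425 without replicate 1 of all groups, 81 without replicate 2 of all groups and 620 without replicate 3 of all groups. The number for GMT versus GT was 1427, against 587 without GMT replicate 2, 452 without GMT replicate 3, 144 without replicate 2 of all groups and 194 without replicate 3 of all groups. For the average effect of adding M it was 4262, against 2806 without replicate 1 of all groups, 2664 without replicate 2 of all groups and 2275 without replicate 3 of all groups. For MT versus T, size factors by RLE gave 951 higher and 376 lower and DESeq2 802 higher and 375 lower. A fit with only GMT and GT called 179. At chr2:84624028-84624336 the T libraries held 3 counts in all and the MT libraries 122. Scaled by the TMM-adjusted library totals, the ratio was 22.4, with an exact 95% counting interval of 7.47 to 110. In edgeR fits (adjusted p in parentheses), the call at chr14:66890247-66890740, MT versus T, was lost without T replicate 1 (0.085), MT replicate 3 (0.0517), replicate 2 of all groups (0.121) or replicate 3 of all groups (0.0878). For GM and G, the call at chr12:33285452-33285984, GM versus G, was lost without replicate 3 of all groups (0.134), and the call at chr2:180301775-180302104, GM versus G, was lost without replicate 3 of all groups (0.195). Likewise, the call at chr15:66629417-66629622, GMT versus GT, was lost without GT replicate 1 (0.177), GMT replicate 2 (0.0523), replicate 1 of all groups (0.22), replicate 2 of all groups (0.0634) or replicate 3 of all groups (0.0552).

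Tbx5 was added to cells with Gata4, Mef2c or both, with the inhibitors in every group. Averaged over the 3 backgrounds, the top-ranked rise was at chr17:73371686-73372265 (log2 fold change 4.22 ± 0.33, adjusted p = 2.97e-10) and the top-ranked fall at chr13:49008796-49009261 (log2 fold change -1.63 ± 0.30, adjusted p = 8.43e-05). Added to G, T gave its top-ranked rise at chr12:33285452-33285984 (log2 fold change 3.69 ± 0.79, adjusted p = 0.00885), from 3.74 ± 3.65 to 33.1 ± 36.8 CPM. Its top-ranked fall was at chr1:89389016-89389242 (log2 fold change -1.94 ± 0.46, adjusted p = 0.0157). On the background of M, T gave its top-ranked rise at chr2:18753102-18753573 (log2 fold change 4.78 ± 0.61, adjusted p = 1.34e-05), from 3.4 ± 2.94 to 111 ± 15.8 CPM. There its top-ranked fall lay at chr13:49008796-49009261 (log2 fold change -2.95 ± 0.55, adjusted p = 0.000456). With the pair GM, T gave its top-ranked rise at chr2:18752751-18752960 (log2 fold change 5.08 ± 0.76, adjusted p = 0.000131), from 1.71 ± 1.6 to 71.3 ± 10.4 CPM. Its top-ranked fall in this case was at chr1:196435845-196436045 (log2 fold change -2.63 ± 0.53, adjusted p = 0.00121). In numbers, 604 regions were higher and 8 lower in GT than in G, 2129 and 424 in MT than in M, 2467 and 348 in GMT than in GM, and 4161 and 1200 for the average effect of adding T. In the same order, loess offsets gave 330 higher and 7 lower, 1568 higher and 825 lower, 1785 higher and 605 lower and, on average, 3513 higher and 2537 lower. Without the library labelled GT replicate 1 the counts were 1860 higher and 581 lower in GT versus G, 2461 higher and 587 lower in MT versus M, 2882 higher and 497 lower in GMT versus GM and 4576 higher and 2102 lower on average. The number called was 612 for GT versus G, against 112 without G replicate 1, 1 without G replicate 3, 0 without GT replicate 2, 199 without GT replicate 3, 1718 without replicate 1 of all groups, 0 without replicate 2 of all groups and 0 without replicate 3 of all groups. That for MT versus M was 2553, against 1246 without M replicate 1, 1282 without M replicate 2, 1683 without MT replicate 1, 1531 without MT replicate 2, 1473 without replicate 1 of all groups, 767 without replicate 2 of all groups and 1255 without replicate 3 of all groups. The number for GMT versus GM was 2815, against 1710 without GM replicate 1, 1343 without GM replicate 3, 1218 without GMT replicate 2, 1639 without GMT replicate 3, 816 without replicate 2 of all groups and 225 without replicate 3 of all groups. For the average effect of adding T it was 5361, against 3233 without replicate 2 of all groups and 3003 without replicate 3 of all groups. A fit with only GT and G called 0 regions by edgeR, with 1277 at an unadjusted p under 0.05, and the fit without GT replicate 2 had 1446. The fits without replicate 2 and without replicate 3 of all groups had 2086 and 1210. DESeq2 with all libraries called 554. In edgeR fits (adjusted p in parentheses), the call at chr12:33285452-33285984, GT versus G, was lost without G replicate 1 (0.0561), G replicate 3 (0.161), GT replicate 2 (0.615), replicate 2 of all groups (0.355) or replicate 3 of all groups (0.634). Likewise, the call at chr1:89389016-89389242, GT versus G, was lost without G replicate 3 (0.284), GT replicate 2 (0.305), GT replicate 3 (0.057), replicate 2 of all groups (0.328) or replicate 3 of all groups (0.742). For GMT and GM, the call at chr1:196435845-196436045, GMT versus GM, was lost without replicate 2 of all groups (0.0522) or replicate 3 of all groups (0.0858).

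The regions higher in a single factor than in the control, 1970 for G, 1982 for M and 2977 for T, were then followed in comparisons that share no library with the one that picked them. This measure was defined after the data were examined. It is the median log2 CPM change from the control mean over those regions, and it was tested with fry, which asks whether the regions move one way on balance, with p-values adjusted over the 30 tests of opened and closed regions. The G-opened regions rose by 0.90 (pooled SD 0.25, 93% of regions higher, adjusted p = 0.00681) in GM over M. Without replicate 3 of all groups, the change at G-opened regions, GM versus M, was 2.26, a value that rests on the 2 regions then higher in G versus control. The G-opened regions rose by 1.19 (pooled SD 0.36, 94.9% of regions higher, adjusted p = 0.00216) in GT over T. Without the library labelled GT replicate 1 that rise was 0.93 (pooled SD 0.21, adjusted p = 0.00904). In GMT over MT the difference was 0.61 (pooled SD 0.27, 82.1% of regions higher, adjusted p = 0.052), and 0.61 with adjusted p = 0.0347 without the library labelled GT replicate 1. The M-opened regions rose by 1.22 (pooled SD 0.22, 95.7% of regions higher, adjusted p = 4.2e-05) in GM over G, by 1.30 (pooled SD 0.21, 96.8% of regions higher, adjusted p = 4.2e-05) in MT over T and by 1.06 (pooled SD 0.25, 92% of regions higher, adjusted p = 0.000148) in GMT over GT. With loess offsets, the change at M-opened regions, MT versus T, was 0.72. The T-opened regions rose by 1.36 (pooled SD 0.18, 93.8% of regions higher, adjusted p = 0.000967) in MT over M and by 1.41 (pooled SD 0.36, 94.7% of regions higher, adjusted p = 0.00115) in GMT over GM. In GT over G they rose by 0.85 (pooled SD 0.52, 92.4% of regions higher, adjusted p = 0.0216), or by 1.25 with adjusted p = 0.000188 without that library and, for the change at T-opened regions, GT versus G, by 0.55 without GT replicate 2 and 1.44 without replicate 1 of all groups. Adding another factor to cells without the factor that opened the regions moved them by -0.04 to 0.11 on the log2 scale. None of those 6 tests passed (adjusted p 0.806 to 0.95). Adding another factor to cells with that factor was not tested in this way. The G-opened regions stood at 1.66 in G, 0.97 in GM, 1.25 in GT (0.99 without the library labelled GT replicate 1) and 0.78 in GMT. The M-opened regions stood at 1.9 in M, 1.16 in GM, 1.28 in MT and 1.03 in GMT. For the T-opened regions the levels were 2.01 in T, 1.01 in GT (SD 0.7), 1.47 in MT (SD 0.24) and 1.53 in GMT (SD 0.5). Without the library labelled GT replicate 1, the level in GT was 1.41 (SD 0.23). The single-factor levels come from libraries that picked the regions. At the regions lower in a single factor, none of the 9 additions of that factor passed (adjusted p 0.146 to 0.892). Of these, 8 had differences below 0, from -0.44 to -0.16, with 16.6 to 39% of regions higher. The value nearest 0, for the G-closed regions in GT over T, was -0.07 with 44.2% higher without the library labelled GT replicate 1. The M-closed regions in MT over T had 0.03, with 49.3% higher. Adding another factor to cells without the factor moved the closed regions by -0.10 to 0.55, and none of those 6 tests passed (adjusted p 0.181 to 0.939). The highest were 0.55 for the G-closed regions in MT over T, with 71.5% higher, and 0.53 for the M-closed regions in GT over T, with 72.2% higher. The G-closed regions stood at -0.57 ± 0.09 (SD, n = 3) in M and at -1.13 ± 0.34 in T relative to the control, and the T-closed regions at -0.60 ± 0.18 in G and -0.74 ± 0.14 in M. Those levels share the control libraries that picked the regions.

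**Figure D3:**
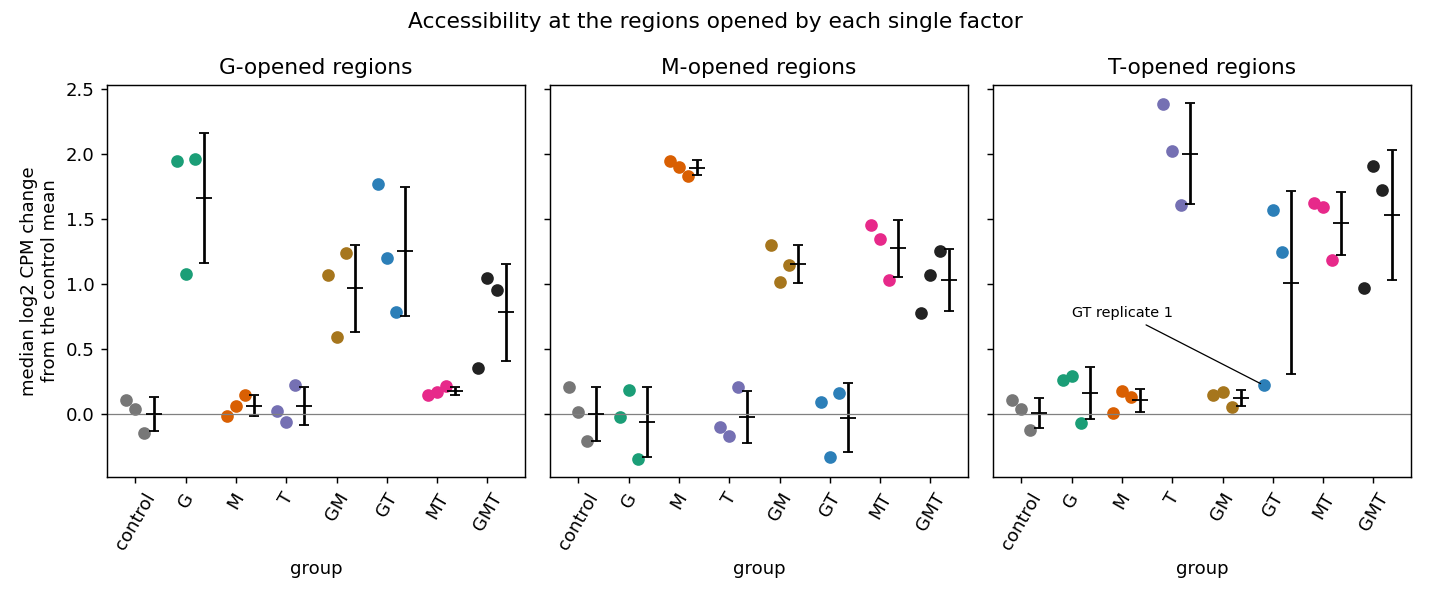
Median log2 CPM change from the control mean (vertical axis) at the regions higher in G, M or T than in the control (panels), 1 point per library in each of the 8 groups (horizontal axis), with the mean and SD of the 3 libraries in black. At the T-opened regions the library labelled GT replicate 1 has 0.22, while the other libraries labelled with Tbx5 have 0.97 to 2.39 and those without it -0.12 to 0.29, and the control, G, M and T points include the libraries that picked the regions.

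Whether a factor's effect depended on another factor was tested by interaction terms between groups that all had the inhibitors. No region passed for M by T in the presence of G, for G by T in the presence of M or for G by M in the presence of T, by edgeR's quasi-likelihood test or by DESeq2, which both called 0. At an unadjusted p under 0.05, edgeR had 749, 889 and 2214 of 20494 regions. Without the library labelled GT replicate 1 it had 824 for M by T and 1355 for G by M, of 21657 regions tested. Without GT replicate 2, the G by M interaction called 21 regions, and without replicate 1 of all groups the G by T interaction called 34. At the opened regions as sets, none of the interaction tests passed either, with differences from -0.58 for G-opened regions in the G by M interaction to 0.56 for T-opened regions in the M by T interaction (adjusted p = 0.949 for both). Those values were -0.32 and 0.16 without the library labelled GT replicate 1 (adjusted p = 0.974 for both).

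Regions where GMT stood above each of GM, GT and MT, all with the inhibitors, numbered 3. At chr9:90108256-90108601, GMT had 113 ± 60.8 CPM (SD, n = 3), against 27 ± 4.63 in GM, 27.8 ± 4.39 in GT and 36.1 ± 11.3 in MT, with log2 fold changes (± SE) of 2.10 ± 0.41 against GM, 2.07 ± 0.41 against GT, 1.66 ± 0.40 against MT and a highest adjusted p of 0.0352. At chr1:195490734-195490934 the log2 fold changes were 1.57 ± 0.52 against GM, 2.18 ± 0.55 against GT, 2.35 ± 0.57 against MT (highest adjusted p 0.0392), and at chr2:102745396-102745889 they were 1.08 ± 0.34 against GM, 1.31 ± 0.34 against GT, 1.39 ± 0.34 against MT (highest adjusted p 0.0389). GMT stood below each pair at chr12:32339627-32339864, with 50.3 ± 15.7 CPM against 100 ± 10.1, 103 ± 24.5 and 104 ± 6.63 CPM (highest adjusted p 0.0433), and at chr1:66863382-66863668, with 78.8 ± 34.8 CPM against 148 ± 29.9, 151 ± 9.12 and 179 ± 19.8 CPM (highest adjusted p 0.0339). These 5 were named whether or not libraries of the groups overlapped. They did at chr9:90108256-90108601 for GMT and MT and at chr2:102745396-102745889 and chr1:66863382-66863668 for GMT and GM. At each of the 5 at least 1 call was lost under other settings, and 0 regions stood above each pair with loess offsets, with only the compared groups in each fit or with a minimum fold of 1.5. The number above each pair was 1 without GM replicate 1, 1 without GM replicate 3, 16 without GT replicate 2, 0 without MT replicate 1, 0 without MT replicate 2, 1 without MT replicate 3, 21 without GMT replicate 1, 0 without GMT replicate 2, 0 without GMT replicate 3, 15 without replicate 1 of all groups, 0 without replicate 2 of all groups and 0 without replicate 3 of all groups. Below each pair there were 4 without GT replicate 1, 0 without GM replicate 1, 1 without GM replicate 2, 0 without GM replicate 3, 0 without GT replicate 3, 0 without MT replicate 1, 0 without MT replicate 2, 0 without MT replicate 3, 23 without GMT replicate 1, 0 without GMT replicate 2, 0 without GMT replicate 3, 38 without replicate 1 of all groups, 0 without replicate 2 of all groups and 0 without replicate 3 of all groups.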

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

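The omission of the library labelled GT replicate 1 from every fit and the changes at opened regions were chosen after the data were examined. With a minimum fold of 1.5, a stricter test, the values were 1777 for G versus control, 2072 for M versus control, 1311 for GM versus control, 2203 for GT versus control, 685 for GM versus G, 203 for GT versus G, 297 for GM versus M, 1602 for MT versus M, 1213 for GT versus T, 556 for MT versus T, 1702 for GMT versus GM, 611 for GMT versus GT, 14 for GMT versus MT, 1436 for average effect of adding G, 1965 for average effect of adding M, 2808 for average effect of adding T, 0 for regions where GMT is above each of GM, GT and MT and 520 for overlap of regions changed by single factors. With only the groups of the contrast in the fit, and so fewer samples, they were 5257 for M versus control, 2531 for GT versus control, 0 for GT versus G, 1581 for GM versus M, 984 for GT versus T, 179 for GMT versus GT, 111 for GMT versus MT, 0 for regions where GMT is above each of GM, GT and MT and 2063 for overlap of regions changed by single factors. Loess offsets gave 337 for GT versus G, 122 for GMT versus MT, 0 for regions where GMT is above each of GM, GT and MT, 0.798 for change at G-opened regions, GT versus T, 0.724 for change at M-opened regions, MT versus T and 1.01 for change at T-opened regions, MT versus M. The replicate number as a block gave 377 for GT versus G. With GT replicate 1 left out of every fit there were 445 for GMT versus MT. No filter on low counts gave 1 for regions where GMT is above each of GM, GT and MT. An adjusted p below 0.01 gave 390 for overlap of regions changed by single factors. The labels do not say what a replicate number marks, and deviations from the group means correlated above 0.1 in 24 of 84 pairs with the same number (median 0.015, from -0.44 to 0.48), so the numbers were not taken as pairs. As a hint of some shared structure, 13 of 24 libraries correlated best with one of their own number. The cause was not tested for loess offsets, the block and the filter. Ranges were taken over fits that left out a single library of the groups that enter a value, or one replicate number of all groups. Fits without a library of another group are outside them, such as M versus control without GT replicate 1. The called regions ran from 2 to 4535 for G versus control, 1104 to 3082 for M versus control and 2361 to 5733 for T versus control. The ranges were 44 to 3132 for GM versus control, 335 to 3982 for GT versus control, 2130 to 5372 for MT versus control and 1271 to 8166 for GMT versus control. Between factor groups the ranges were 72 to 2157 for GM versus G, 0 to 2441 for GT versus G, 38 to 1062 for GM versus M, 767 to 2296 for MT versus M, 271 to 3022 for GT versus T, 81 to 1830 for MT versus T, 225 to 3498 for GMT versus GM, 144 to 1774 for GMT versus GT and 0 to 674 for GMT versus MT. They were 2150 to 4874 for average effect of adding G, 2275 to 5382 for average effect of adding M, 3003 to 6678 for average effect of adding T, 0 to 0 for M by T interaction in the presence of G, 0 to 34 for G by T interaction in the presence of M, 0 to 21 for G by M interaction in the presence of T, 0 to 21 for regions where GMT is above each of GM, GT and MT and 220 to 1451 for overlap of regions changed by single factors. For the remaining values they were 0.761 to 2.26 for change at G-opened regions, GM versus M, 0.891 to 1.41 for change at G-opened regions, GT versus T, 0.447 to 0.881 for change at G-opened regions, GMT versus MT, 1.04 to 1.72 for change at M-opened regions, GM versus G, 1.14 to 1.87 for change at M-opened regions, MT versus T, 0.867 to 1.33 for change at M-opened regions, GMT versus GT, 0.552 to 1.44 for change at T-opened regions, GT versus G, 1.26 to 1.64 for change at T-opened regions, MT versus M and 1.19 to 1.79 for change at T-opened regions, GMT versus GM. The 2.26 for change at G-opened regions, GM versus M, rests on the 2 regions higher in G versus control without replicate 3. The other changes at G-opened regions in that setting rest on the same 2. Of 780 values of named regions under other settings, 735 kept their direction and their call, 45 kept their direction and lost the call and 0 reversed. Those settings include fits of other groups with GT replicate 1 left out. With a single library of the compared groups or a replicate number left out, 674 of 801 kept both, 127 lost the call and 0 reversed. The regions were picked for called changes in these same data, and most also for libraries that do not overlap between groups. The lack of reversals was therefore largely set in advance and says little about stability. The spread between libraries, as the mean correlation of log2 CPM within groups, was 0.864, and 0.885 with a prior count of 5. The other control group, the inhibitor effect, gene lists, motifs and start-site distances were not run, and changes at opened regions have no value with only the groups of the contrast.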

Other observations

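The tests at regions higher in MT than in M, of G at regions lower in M and T, of neighbouring regions and of other splits were set before their values were seen, and the tests of a swap, of weak signal, of the shared control, of the mean count, of the count trend and of few counts after. Neighbouring pairs of opened regions within 10 kb numbered 106 for G, 82 for M and 330 for T. Random draws of as many tested regions within chromosomes gave at most 69, 65 and 135 in 1000 draws. For closed regions the pairs numbered 34, 39 and 78, against at most 32, 34 and 85. The draws were matched on chromosome only, while the median width of opened regions was 276 bp in G, 283 bp in M and 313 bp in T, against 260, 259 and 255 bp for regions not called. The counts of opened regions met the prediction, but they restate the pattern, so the outcome was set to undecided after the values were seen.

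The library labelled GT replicate 1 had a T-opened score of 0.22, against 1.57 and 1.25 in the other GT libraries. A swap with another of the 24 libraries analysed lacked its partner. The highest score among the 12 libraries labelled without Tbx5 was 0.29 and the lowest of the other 11 with Tbx5 was 0.967. The 3 samples without a column could not be checked. Weak signal or low depth was excluded by its G-opened score of 1.77, above 1.20 and 0.79. At 609 regions higher in MT than in M and not called in T, its median log2 change from G was -0.021, within the G libraries (-0.091 to 0.21) and below 0.84 and 0.71 in the other GT libraries. A wrong label or cells without active Tbx5 may account for it, and no value here separates those explanations.

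More regions were lower than the control in several single factors than independent lists give. Covariances of the log2 fold changes were 0.34 for G and T and 0.35 for M and T, against at most 0.19 in simulated unchanged groups. This excluded the shared control as the whole source of the covariance in those pairs, and left it open for G and M at 0.17. Covariances span rises and falls at all regions tested, and those simulations hold no effects. The shared control was therefore not excluded as a source of the shared lower regions. M and T shared 648 lower regions and random lists matched on mean count at most 219. That mean spans all libraries and a fall lowers it, so the level in the control was not matched. Regions lower in M and T had median control levels of 58.4 and 51.3 CPM, against 21.2 and 20.7 CPM for those not called. Calls at regions with more counts in the control therefore remain open. A trend with the mean count was excluded as the whole source, since loess offsets left 1226 regions lower in 2 or 3 factors. At the 648 regions the median log2 change of G from the control was -0.61, with 77.5% of regions lower. Simulations with only G unchanged, and M and T at their fitted levels, gave -0.19 on average at the regions then lower in both. They took the fitted control level as true, so chance highs of the control libraries counted as real falls. The value may therefore understate what the shared control gives. The inhibitors were given to every factor group and not to this control. They and an effect common to the factors could each give the lower level of G, and part of it may come from the shared control. The design ties the inhibitors and a common effect together, so these cannot be told apart.

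More regions were higher than lower in GMT than in the control, 68.7% of those called. Simulated changes of equal number and size in both directions gave 69.6% higher among those called at a fold of 4. At a fold of 2 it was 50%, where 4 were called each way. The simulation tested 14187 regions after its own filter, and changed regions lost there counted as not called. Raised regions pass that filter more easily, so the simulated share may come partly from it. Falls that are harder to call could still account for the imbalance. Among regions with a mean CPM at or above the median the share was 68.5%, which excludes nothing, since the change itself raises the mean. With loess offsets it was 53.7%, so a trend of the fold change with the mean count could also account for much of it, though loess offsets presume that changes balance at each count level. These explanations and a true excess of opened regions cannot be told apart, since no value here separates them.

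Other splits of the same libraries were tested for each count. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real count and the highest of the other splits were 3213 and 1 for G versus control, 3308 and 0 for M versus control, 5153 and 0 for T versus control, 2510 and 0 for GM versus control, 3872 and 727 for GT versus control, 5053 and 0 for MT versus control and 6869 and 1560 for GMT versus control. Between factor groups they were 1490 and 1 for GM versus G, 926 and 0 for GM versus M, 2553 and 0 for MT versus M, 2599 and 1 for GT versus T, 1323 and 0 for MT versus T, 2815 and 70 for GMT versus GM, 1427 and 514 for GMT versus GT and 202 and 1 for GMT versus MT. For GT versus G, 2 of 10 splits gave at least the real 612, and the split of G replicates 1 and 3 with GT replicate 1 against the other 3 gave 2827, which points to a structure of the samples. Over 25 splits, including the real one, only the real one reached its count for the averages, a share under 0.05. The real count and the highest of the others were 4555 and 806 for average effect of adding G. They were 4262 and 617 for average effect of adding M and 5361 and 1 for average effect of adding T. That share is the lowest 25 splits can give, and mixing groups that differ widens the spread within them. The splits therefore do not exclude chance. For the interactions, where the real count was 0 by edgeR and DESeq2 and 749, 889 and 2214 regions had an unadjusted p under 0.05, every split gives at least as many as 0, so the splits tested nothing about chance. The highest of the others were 2874, 2646 and 1665. Those splits mix libraries of different factor groups, so the factor effects themselves enter the interaction term there. For regions where GMT is above each of GM, GT and MT, 2 of 25 gave at least the real 3, with a highest of 44, so chance was not excluded.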
